A study of Homo sapiens with 12 samples.

How the data were processed

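Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on UMUC3-c31 cells. UM-UC-3 is an established human bladder carcinoma cell line, and the labels do not say what c31 stands for. Per the labels' protocols, cells were kept for 24 h in charcoal-stripped serum, treated for 24 h, and fixed in 1% paraformaldehyde. Chromatin was sheared and precipitated with a rabbit antibody to the androgen receptor (AR) or with normal rabbit serum, and sequenced as single reads of 50 nt. The 12 samples fall into 4 groups: 5 AR precipitations from cells treated with R1881, 5 control precipitations (IgG in the labels) from unstimulated cells, and 1 input from each condition. Treatment and antibody change together between the precipitated groups. The labels call the 10 precipitated samples biological replicates.

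The deposited processed data are one peak list for the whole series, with 4 columns per line: chromosome, start, end and peak name. The list gives no score, height, enrichment, p-value or read number, so the depth of the libraries and of each peak is unknown here. Novoalign and MACS2 are named in the submitters' processing notes, without versions or settings, and the caller's threshold is not given in the sources used here. Each peak name carries a call number from 1 to 5, words saying that input was subtracted, a peak number and, where a peak has several summits, a letter. The authors thus deposited peaks per call, and which libraries entered each call is not given in the sources used here. The list as a whole is labelled as AR peaks by the submitters. The peak names give no antibody or treatment, and replicate numbers 1 to 5 exist in the AR group and in the IgG group alike, so no call was assigned to a sample. Calls are described one by one, with medians and ranges and without a standard deviation. The 22338 lines are summit entries, which reduce to 19816 peaks when entries of one call with an identical interval are counted once. Of the peak numbers of the 5 calls, 36 are absent from the list, and no peak lies on an unplaced contig.

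The submitters' processing notes name the build hg38 (GRCh38). The positions were checked against the chromosome lengths of 3 human builds held in the R package GenomeInfoDb 1.38.1. In GRCh38, 417 peaks on 10 chromosomes end past the end of their chromosome, by up to 2112 kb, and each of the 5 calls holds such peaks. In the older NCBI36 the number is 453. In GRCh37 (hg19) it is 0. GRCh37 chromosome lengths were therefore used. The list counts starts from 0, as BED files do, and printed starts are 1 higher, so that positions are 1-based. A gene table of GRCh38.p14 was used only for the number of protein-coding genes per chromosome. No GRCh37 sequence or annotation was used here, so the planned tests of genomic features, DNA motifs, gene lists and nearest genes were not run. The planned test of AR against IgG libraries was not run either, since the list holds no value per library. The rule for named genes, fixed before the data were examined, named CD44, the best-placed members of each gene list and the genes nearest to the 20 widest peaks. Only CD44 and, in place of genes, the widest regions are named. The planned window around CD44 was replaced by the 1 Mb bin that holds the gene. Overlap between calls, width by support, neighbour distances, gene density, the random placements for bins and the Y stretch were examined by choices made after the data were seen.

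Peaks of all calls that overlap by at least 1 bp were merged into regions, and the support of a region is the number of calls with a peak in it. For each ordered pair of calls, the share of peaks of one call that overlap a peak of the other was computed with its exact (Clopper-Pearson) 95% interval. It was set beside 1000 placements at uniform random positions of the same chromosome and 1000 placements shifted by 10 to 50 kb. Width was related to support within each call by Spearman's rho with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over the 5 calls. Regions were counted per chromosome, with exact 95% Poisson intervals, and in bins of 1 Mb by their midpoint. Random positions include assembly gaps, because no gap table was used here. Intervals cover counting error only. Peaks and regions along a genome are not independent replicates. The overlap and neighbour functions were tested on simulated data: of 400 regions planted in all 5 simulated calls among 3990 sites, 400 were recovered, and a planted neighbour share of 18.2% among 550 positions was recovered as 18.2%. Alternatives were merging within 500 bp or 2 kb, other support thresholds, other bin widths and distances, an overlap of at least 50% of the shorter peak, and leaving out each call. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.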

Results

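AR binding was studied by ChIP-seq in UMUC3-c31 bladder cancer cells treated with R1881, a synthetic androgen. AR is a hormone-activated transcription factor that binds DNA when an androgen occupies it. The title of the series names CD44, a cell surface receptor for hyaluronan, as the gene whose direct regulation by AR is in question. Of the 12 samples, 5 were AR precipitations after R1881, 5 were IgG precipitations without stimulation, and 2 were inputs. As labelled, no sample is an AR precipitation from unstimulated cells or an IgG precipitation from R1881-treated cells. The design text of the series describes the conditions only as ethanol vehicle and R1881, and does not mention the antibody. The processed data were peaks of 5 separate calls, each named as having input subtracted. The list as a whole is labelled as AR peaks. The peak names give neither antibody nor treatment, so no call was tied to a sample. The list holds no read numbers, so the depth behind each peak is unknown, and no peaks identified as IgG background were analysed here. A test of R1881 with AR antibody against unstimulated with IgG was not possible from peak positions alone.

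The 5 calls held between 825 and 6607 peaks, with a median of 4315. Call 1 had 6607 peaks, call 3 had 4937, call 2 had 4315, call 4 had 3132 and call 5 had 825. The largest call thus held 8.01 times as many peaks as the smallest, and 9.21 times as many on chromosomes 1 to 22 and X. The median peak was 254 bp wide in call 1, 226 bp in calls 2 and 3, 222 bp in call 4 and 129 bp in call 5. On chromosomes 1 to 22 and X, the peaks covered 1873 kb in call 1, 1109 kb in call 2, 1254 kb in call 3, 761 kb in call 4 and 102 kb in call 5. Between 5.21% and 5.65% of the peaks of calls 1 to 4 had more than 1 summit, against 29.5% in call 5.

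Most regions were found in more than 1 call. Merged peaks formed 8005 regions covering 2430 kb, of which 4951 (61.8%, 95% interval 60.8 to 62.9%) were found in at least 2 calls and 2290 (28.6%) in at least 4. All 5 calls shared 642 regions, 621 of them on chromosomes 1 to 22 and X. A further 1648 regions were found in 4 calls, and in 1622 of these (98.4%) the missing call was call 5. Of the 3054 regions found in 1 call, 1804 came from call 1, 682 from call 3, 398 from call 2, 156 from call 4 and 14 from call 5.

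Peaks of the smaller calls lay mostly within those of the larger ones. Over the 10 pairs of calls, the share of peaks of the smaller call that overlapped a peak of the larger ranged from 77.5% to 97.3%, with a median of 87.7%. In the other direction it ranged from 11.2% to 67.5%. Call 5 peaks overlapped a call 1 peak in 740 of 825 cases (89.7%, 95% interval 87.4 to 91.7%). This share was 97.0% on chromosomes 1 to 22 and X. Call 4 peaks overlapped a call 1 peak in 2853 of 3132 cases (91.1%). The random placements were made on chromosomes 1 to 22 and X only, and set beside the observed shares there. Peaks shifted at random by 10 to 50 kb overlapped the other call in at most 1.42% of cases over all 20 ordered pairs. On these chromosomes every observed share was above every one of its 1000 placements (p = 0.001, the smallest these placements can give, one-sided permutation test).

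**Figure D1:**
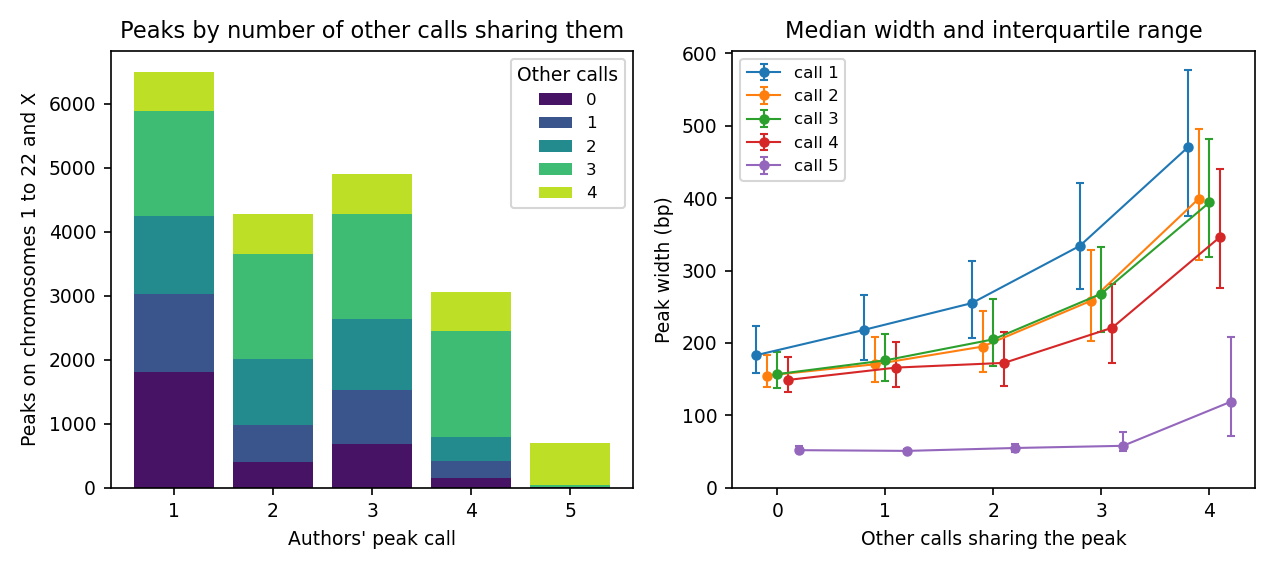
Left, number of peaks on chromosomes 1 to 22 and X in each of the authors' 5 calls, coloured by how many of the other calls have an overlapping peak. Right, median peak width in bp by the number of other calls that share the peak, with bars for the interquartile range and points set apart sideways for legibility. In call 1 the median width is 183 bp for the 1804 peaks found in no other call and 470 bp for the 620 peaks found in all 4 other calls.

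Regions shared by more calls had wider peaks. In call 1, peaks found in no other call had a median width of 183 bp (interquartile range 158 to 224 bp), and peaks found in all 4 others had a median of 470 bp (376 to 577 bp). In call 4, the medians were 149 bp for 153 peaks and 347 bp for 618 peaks. Spearman's rho between width and the number of other calls, across peaks on chromosomes 1 to 22 and X, was 0.68 in call 1, 0.63 in call 2, 0.65 in call 3, 0.58 in call 4 and 0.31 in call 5. The permutation p was 1e-05 in each call, the smallest that 100000 permutations can give, and 1e-05 after adjustment over the 5 calls. In call 5, 657 of 706 peaks were found in all 4 others, so its other classes hold 30 peaks or fewer.

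On chromosomes 1 to 22 and X, the widest region common to all 5 calls lay on chromosome 13 from 45495766 to 45497003 and spanned 1238 bp. The next were on chromosome 20 from 47998118 to 47999259 (1142 bp), on chromosome 1 from 172714933 to 172716066 (1134 bp) and on chromosome 1 from 109370938 to 109372037 (1100 bp). The regions named on chromosomes 13 and 20 each joined 9 peaks of the 5 calls, and those on chromosome 1 joined 6 each. Region width is thus not the width of a single peak. Chromosome 20 held 4 of the 20 widest common regions on chromosomes 1 to 22 and X, with others at 48036862 to 48037807, 43342792 to 43343700 and 43095753 to 43096641. Chromosomes 5 and 11 held 3 each, and 2 of those on chromosome 11 lay close together, at 114033295 to 114034379 (1085 bp) and 114049786 to 114050681 (896 bp). These belong to the only place on chromosomes 1 to 22 and X where 3 or more regions common to all 5 calls followed each other within 20 kb: 4 such regions lay between 114030565 and 114050681 on chromosome 11, a span of 20.1 kb. This place was singled out after its values were seen. With no annotation of the build, the genes at these regions are not named.

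Regions were unevenly spread over the chromosomes. Chromosomes 1 to 22 and X together held 2.62 regions per Mb, and the median chromosome held 2.79. Among these, with the Y chromosome left out, chromosome 17 (4.06 per Mb, 95% interval 3.64 to 4.53) and chromosome 20 (3.92, 3.45 to 4.44) had the highest densities. The X chromosome (0.89, 0.75 to 1.05) and chromosome 18 (1.59, 1.32 to 1.89) had the lowest. For regions in at least 4 calls, chromosome 20 ranked first with 1.40 per Mb (1.12 to 1.72) against a median of 0.77, and the X chromosome last with 0.23 (0.16 to 0.31). These lengths include assembly gaps, and the intervals cover counting error only. Copy number was not examined, and the densities are not corrected for it. Each call gave the X chromosome a similar share of its peaks, from 1.38% in call 2 to 1.77% in call 3.

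**Figure D2:**
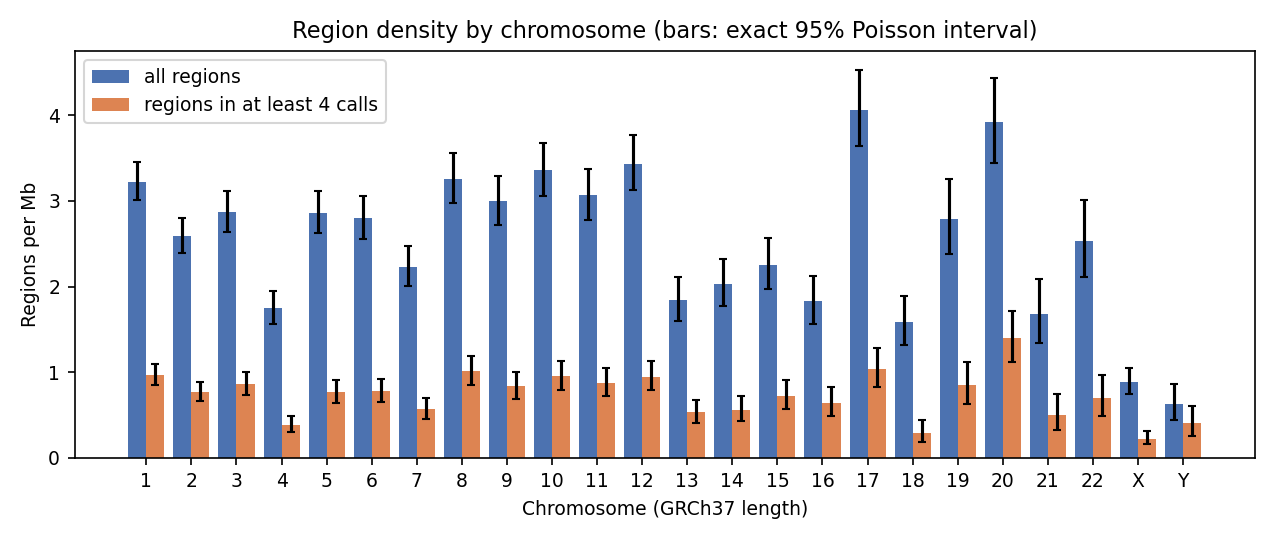
Regions per Mb of GRCh37 chromosome length, for all regions (blue) and for regions found in at least 4 calls (orange), with exact 95% Poisson intervals. Chromosomes 17 and 20 stand highest for all regions, and chromosome 20 for regions in at least 4 calls (1.40 per Mb). Of the 24 Y regions in at least 4 calls, 22 lie in one stretch of 98.3 kb.

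Across 23 chromosomes (1 to 22 and X), regions per Mb were compared with protein-coding genes per Mb, and the rank correlation passed the threshold narrowly while the linear one did not reach it. Spearman's rho was 0.42 (permutation p = 0.0482) and Pearson's r was 0.35 (permutation p = 0.0999). Without chromosomes 17 and 19, which lie farthest from the median gene density, rho was 0.37 (permutation p = 0.0952) and r was 0.42 (permutation p = 0.0594), so the rank correlation was no longer past the threshold with 21 chromosomes, while both coefficients stayed of similar size. For regions in at least 4 calls rho was 0.47 (permutation p = 0.0222) and r was 0.35 (permutation p = 0.104). This was the only relation of this kind computed. Chromosome 19 held 11.4 regions per 100 protein-coding genes and chromosome 8 held 66.8.

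Regions also gathered locally. The densest 5% of the 3053 bins of 1 Mb held 23.02% of the regions, against at most 13.6% in 100 random placements. With bins of 5 Mb the share was 14.7%, against at most 9.78% in 100 random placements. Bins of 1 Mb with at least 10 regions numbered 134, against at most 9 in those placements, and 977 bins held none. The fullest bins were chromosome 12 from 43 to 44 Mb with 22 regions, chromosome 20 from 49 to 50 Mb with 21, chromosome 1 from 64 to 65 Mb with 20 and chromosome 11 from 12 to 13 Mb with 20. By regions in at least 4 calls, chromosome 20 from 49 to 50 Mb led with 10, followed by 9 each on chromosome 20 from 48 to 49 Mb, chromosome 8 from 131 to 132 Mb and chromosome 12 from 94 to 95 Mb.

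The megabase of chromosome 11 from 35 to 36 Mb, which holds CD44, contained 12 regions. That CD44 lies in this bin in GRCh37 as well as in GRCh38 is background knowledge and not a result from the list. The counts describe the whole bin and not CD44 itself, and the distance of each region from the gene was not measured. The median bin held 2 regions, on chromosome 11 as over all bins, and 72 of the 3053 bins (2.36%) held at least 12. Of the 12 regions, 6 were found in 1 call and 6 in at least 2. The regions with the widest support were at 35929381 to 35930106, found in all 5 calls and 726 bp wide, at 35236239 to 35236556 (318 bp) and at 35448806 to 35449081 (276 bp), these last in calls 1 to 4. As many as 3 regions in at least 4 calls occurred in 264 bins (8.65%).

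In the first part of that bin, 4 further regions had less support. The region at 35160680 to 35160813 was found in call 2 alone, the one at 35165857 to 35166222 in call 3 alone, the one at 35188156 to 35188420 in calls 1 and 3, and the one at 35190370 to 35190516 in call 1 alone. Counted by call, the bin held 9 peaks in call 1, 6 in calls 2 and 3 each, 4 in call 4 and 1 in call 5. Whether a region lies in the promoter, an exon or an intron of CD44, or in a neighbouring gene, was not analysed here. No GRCh37 annotation and no conversion between builds was used.

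**Figure D3:**
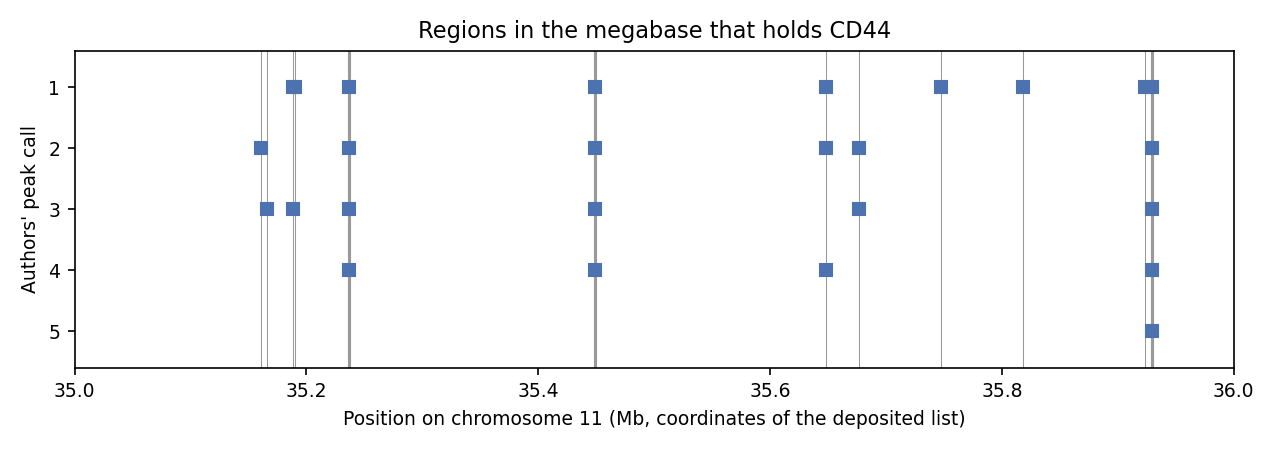
Regions on chromosome 11 between 35 and 36 Mb, in the coordinates of the deposited list. Each square marks a region in which that call has a peak, drawn at the region's midpoint, and thick vertical lines mark the 3 regions found in at least 4 calls; the 12 regions include 6 found in 1 call.

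The Y chromosome differed from all others in that one stretch took nearly all of its entries. Between 58819381 and 58917705, a span of 98.3 kb near the end of the long arm, peaks formed 27 regions, 21 of them found in all 5 calls, and covered 97.2% of the stretch. The widest single peak there measured 10458 bp, against 1775 bp for the widest on chromosomes 1 to 22 and X. Call 1 had no peak wider than 1775 bp on any chromosome. The widest peaks of calls 2 to 5 measured 10458, 10113, 6175 and 5379 bp. Call 1 peaks covered 1911 kb over all chromosomes and 1873 kb on chromosomes 1 to 22 and X. What remains is shorter than the stretch, so call 1 alone did not cover it to this extent. This stretch took 1.76% of the summit entries of call 1, 5.98% of call 2, 5.23% of call 3, 8.21% of call 4 and 41.2% of call 5 (641 of 1554, 95% interval 38.8 to 43.7%). Counted by distinct peaks in place of summit entries, its share of call 5 was 13.7%. On that count it was 1.53% in call 1, 0.70% in call 2, 0.51% in call 3 and 1.79% in call 4. Outside it, the Y chromosome held 10 regions, of which 2 were found in at least 4 calls.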

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

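The tests on peak number and on the Y chromosome in this part were chosen after the values were seen. Of 8 measures compared over the 5 calls, 4 set call 5 apart from the others by Dixon's criterion: its median peak width of 129 bp (222 to 254 bp in the others), its narrowest peak of 49 bp (128 to 147 bp), its 29.5% of peaks with more than 1 summit (5.21% to 5.65%), and the 41.2% of its entries in the Y stretch (1.76% to 8.21%). Chance sets about 1 in 20 such groups apart, and the measures are related to each other. Its peak number of 825 did not meet the criterion. Peaks on the mitochondrial chromosome, which are counted among the 8005 regions but enter no comparison of chromosomes, were present in call 3 (6 peaks) and call 4 (8 peaks), and 4 of their 9 merged regions were common to both calls. The other 3 calls listed none, and no peaks identified as control were analysed here.

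The calls differed 8.01 times in peak number, and the peaks found in call 1 alone are not as strong as its shared peaks if width stands for strength: their median width was 0.63 of that of the shared ones (183 against 289 bp). For the smallest and the largest call, 97.0% of call 5 peaks on chromosomes 1 to 22 and X overlapped a call 1 peak. There the values are those that the same sites seen at different sensitivity would give. Over all chromosomes the share was 89.7%. The Y stretch went the other way, with 641 summit entries and 113 peaks in call 5 against 123 and 101 in call 1. Lower sensitivity of call 5 alone does not account for the stretch. Over the 10 pairs the share of the smaller call in the larger went down to 77.5% (call 2 in call 3), so not every pair came as close. Against call 1, the largest, it was 85.7% for call 2, 81.7% for call 3 and 91.1% for call 4. For call 5 a shorter assumed fragment length stays open as well: its narrowest peak was 49 bp, close to the 50 nt read length, and 55 of its peaks had that width. Every other call also had many peaks at its own narrowest width. These were 306 at 147 bp in call 1, 227 at 134 bp in call 2, 293 at 134 bp in call 3 and 165 at 128 bp in call 4. Whether a shorter length lowered the peak number of call 5 cannot be told apart from lower depth or enrichment without the reads. A biological difference between the cultures was not tested.

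The Y stretch was present in every call and took the largest share of the call with the fewest peaks. The whole Y chromosome held 0.62 regions per Mb (95% interval 0.44 to 0.86), below the median of 2.79 on chromosomes 1 to 22 and X. This interval overlaps that of the X chromosome (0.89, 0.75 to 1.05), but 27 of the Y regions lie in the stretch. Outside the stretch the Y chromosome held 10 regions, or 0.17 per Mb (0.08 to 0.31), below the X interval. The stretch was set apart after it was seen, which by itself lowers the density of the rest, and the lengths are not corrected for gaps. These values therefore do not decide whether the rest of the Y chromosome holds regions like the others. For regions in at least 4 calls the whole Y chromosome held 0.40 per Mb (0.26 to 0.60) and the X chromosome 0.23 (0.16 to 0.31). Of the 24 such Y regions, 22 lay in the stretch and 2 outside it. All these lengths include assembly gaps. Reads from many copies of a repeat piling up on one assembled stretch stay open as an explanation. Peaks covered 97.2% of the stretch, and its widest peak measured 10458 bp, against 1775 bp on chromosomes 1 to 22 and X. The ends of the stretch were set from the peaks, which does not by itself force such a coverage. The bounds for both values were set after they were seen, so they do not decide the question. Binding of AR to such a repeat was not tested, and both cannot be told apart without the reads or peaks identified as IgG background.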

How the results depend on the processing

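Of 50 alternatives, 26 left their result within its margin (1.5 times for a count, the 95% interval for a share), 23 moved it and 1 left a correlation no longer past its threshold; only merging within 500 bp, restriction to chromosomes 1 to 22 and X in the number of regions, and 5 Mb bins were chosen before the data were examined, and the others after. The number of regions was 4031 when only the wider peaks of each call were kept, which removes peaks by construction. The share of regions in at least 2 calls was 63.3% after merging within 500 bp and ranged from 56.2% to 61.9% when each call was left out. On chromosomes 1 to 22 and X, 97.0% of call 5 peaks overlapped call 1 and 9.87% of call 1 peaks overlapped call 5. The CD44 bin held 6 regions in at least 2 calls and 3 in at least 4, and 8 regions without call 1. The densest 5% of bins held 14.7% of regions with 5 Mb bins, 25.4% of those in at least 2 calls, 31.02% of those in at least 4, and from 23.03% to 24.0% when each call was left out. Fewer regions per bin raise this share by themselves. No random placements were made for the sets by support, so their higher shares do not show stronger gathering. The share of regions with another within 10 kb was 25.9%. It was 17.6% within 5 kb, 53.1% within 50 kb, 21.3% and 16.0% after merging within 500 bp and 2 kb, 18.3% and 10.5% for regions in at least 2 and at least 4 calls, and 22.7% to 25.9% when each call was left out. Spearman's rho of region and gene density was 0.37 without chromosomes 17 and 19 (permutation p = 0.0952), no longer past the threshold, and the cause was not tested. It was 0.47 (permutation p = 0.0222) for regions in at least 4 calls and 0.48 (permutation p = 0.0232) over the span from the first to the last region, where Pearson's r was 0.35 (permutation p = 0.104) and 0.38 (permutation p = 0.0801). The Y stretch took 13.7% of call 5 when peaks were counted in place of summit entries, against 0.51% to 1.79% of the other calls on that count. No paired analysis was possible because the list holds no value per library. Not run were the alternatives based on a peak score, on annotated features, on motifs, on gene lists, on windows around CD44 itself, and on the test of AR against IgG. The depth of the libraries is unknown and limits every count of peaks.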

Other observations

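Regions tended to have a close neighbour. On chromosomes 1 to 22 and X, 2060 of 7959 regions (25.9%) had another region within 10 kb, against a mean of 5.53% and at most 6.45% in 100 uniform random placements. Among the 2266 regions in at least 4 calls, 238 (10.5%) had another such region within 10 kb, against at most 2.74%. The close-neighbour share and the shares and widths by call were chosen after the data were seen. The bounds for both tests of an explanation of that share were set before their results were seen.

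Uneven density between bins of 1 Mb is argued against as the whole account: positions drawn within the same 1 Mb bins gave a mean share of 10.1% and at most 11.2%. Copy number or gene density that varies within a bin was not tested, since positions were drawn evenly inside each bin. One site split into several intervals is also argued against as the whole account, since 16.0% had a neighbour after intervals within 2 kb were merged, against at most 5.94% in random placements. Each may explain part of the share, as the lower values show. Both acting together were not tested, since merged regions were not set beside positions drawn within the same bins. Clustering of receptor sites at regulatory regions is a biological hypothesis that stays open, since no annotation of the build was used.

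Call 5 gave chromosome 22 a share of 3.82% of its peaks on chromosomes 1 to 22 and X (27 of 706, 95% interval 2.54 to 5.52%), against 1.37% to 1.69% in the other calls. It gave chromosome 16 a share of 3.54% (25 of 706, 2.30 to 5.18%), against 2.15% to 2.28%. Other shares were lower in call 5, such as that of chromosome 18 (0.57%, against 1.16% to 1.57%) and that of chromosome 17 (2.97%, against 3.94% to 4.28%). These were chosen after the values were seen, among 23 chromosomes.

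Within the 563 regions of chromosomes 1 to 22 and X that held exactly 1 peak of each call, call 1 peaks had a median width of 463 bp, call 2 of 396 bp, call 3 of 385 bp, call 4 of 343 bp and call 5 of 129 bp. The median difference between call 1 and call 5 was 307 bp (interquartile range 237 to 394 bp), more than the 98 bp between their narrowest peaks.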
